A study of Mus musculus with 6 samples.

How the data were processed

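The data were polyA RNA sequencing counts from 6 libraries of mouse primary vascular smooth muscle cells, 3 labelled as negative control and 3 as transfected with siRNA against Arid3a. Per the labels' protocols, mRNA was captured from 1 µg of total RNA and sequenced on an MGI instrument. The authors deposited whole-number read counts per gene for each library, with gene identifiers, symbols, positions and lengths. Reads were aligned with STAR 2.7.3a to mm10 and counted with featureCounts, per the submitters' processing notes. The annotation, the strand setting and any read filter are not given in the sources used here. Every one of the 23197 genes listed had at least 1 count over the 6 libraries, so genes with 0 counts in all libraries have no row in the table.

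The length column of the deposited table equals the whole span from the start to the end of the gene in all 23197 rows, introns included. This was followed up with GENCODE M21 on GRCm38, the same assembly as mm10. Of the identifiers 23134 were in it, 22915 with the same start and end, and it named 4530 of the 4577 rows that have no symbol. Of 1509 protein-coding genes with all exonic bases under the span of another gene, 13.8% were listed, against 80.0% of the other 20442. Of 789 covered by opposite-strand genes only, 6.08% were listed. These shares are what counting over whole gene spans without strand would give. A gene's count can then hold intronic reads, and reads in shared spans are lost, so genes such as Timp1, Timp3, Ccl2, Cxcl10 and Tk1 were not analysed here. The share of exonic bases outside other genes is given beside Avil, Tagln, Psmb8, Ccne2, Gadd45a, Trim14 and C1s1. Of the other tested genes named, it was under 90% for Ftl1 (65.4%), Ncam1 (66.7%), Ccnd2 (71.3%), Loxl3 (71.8%), Tnnt3 (73.5%), Mylk (75.3%), Tmem176b (76.3%), Spp1 (81.2%), Pkm (84.7%), Ppp1r15a (86.1%), Ctsb (87.2%) and Tmem47 (88.5%). Reads of paralogs, such as members of the Ifit, Oas and ribosomal protein families, can be split by counting.

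Total counts ranged from 17029735 to 22799935 per library. Genes were kept by filterByExpr of edgeR, which left 13234. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and a second count asked for at least a 2-fold change. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Levels are CPM, counts divided by the TMM-scaled library total, as mean ± SD of 3 libraries. For pairs of libraries within a group, the chi-square of the counts per degree of freedom was 6.08 to 22.1, so every pair differed by more than sampling noise.

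A total of 32 gene lists, 8 of them of cell types a culture could also hold, were fixed before the data were examined, as were the tests and the alternatives unless stated. Lists were tested with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. An estimated correlation and the rotation test fry were run beside it. List medians are medians of the edgeR log2 fold changes. The pericyte, macrophage, epithelial, fibroblast, endothelial, adipocyte, neural and striated muscle lists are the cell type lists. Fn1 is in both the matrix and the fibroblast lists.

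The named genes follow a rule set in advance: Arid3a; Acta2, Tagln, Myh11 and Cnn1; up to 12 called genes in each direction or, since 0 passed, the 10 with the smallest p; and up to 4 called members of each list or, since 0 passed, the 2 with the highest mean expression. Irf7, Irf1, Oas2, Psmb8, Psmb9, Lcn2, Vcam1, C3, Cxcl1, Pdk1, Pfkl, Tpi1, Ccne2, Ppp1r15a, Agt, Gadd45a, Steap4, Loxl3, Fos, Fosb, Apol8, C1s1, Neto2, Trim14 and Tdg were chosen after their values were seen. Some genes that were analysed are not reported here.

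The alternatives were other scalings (RLE, upper quartile, library size), DESeq2 1.42.0, limma-voom, other filters on low counts, a non-robust fit, a replicate block, a stricter threshold and each library left out in turn. Removal of each library's loess trend of log2 CPM with GC content and transcript length, a block for library depth and a restriction to genes with at least 90% of their exonic bases outside other genes were chosen after seeing the data. The fits were tested on simulated counts for the comparison of siArid3a with control over 13234 genes, with 50 genes changed at each fold. edgeR recovered 70%, 78%, 94% and 100% of the genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, with 15 false calls, and DESeq2 recovered 66%, 76%, 94% and 100%, with 20 false calls. limma-voom recovered 68%, 80%, 94% and 100%, with 15 false calls. With 200 changed genes in the simulation the adjusted threshold is easier to pass, so these shares do not give the power where few genes change strongly. In a second simulation, camera called an interferon list shifted by −0.3 and 0 of the other lists. That result does not give the rate of false list calls in these libraries, where a split mixing the groups gave 13 lists. The estimated correlation ranged from −0.08 for the neural list to 0.82 for the ribosomal protein list. It was 0.57 for the interferon list and 0.27 for the inflammatory list, both above the preset value.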

Results

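RNA was sequenced from cultured mouse primary vascular smooth muscle cells, the contractile cells of the artery wall, after transfection with an siRNA against Arid3a or a negative control. Arid3a is a DNA-binding protein of the AT-rich interaction domain family. The labels give 3 control libraries and 3 libraries labelled siArid3a, with 24 h of incubation after transfection. Control libraries 1, 2 and 3 held 19079970, 22189166 and 17057300 gene counts, and siArid3a libraries 1, 2 and 3 held 22799935, 17029735 and 19585920. The labels number the siArid3a libraries #1 to #3 without saying whether these are different siRNAs or repeats, and they name no separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The labels also describe angiotensin II treatment of such cells, without saying whether these libraries received it.

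The first comparison was a check of the targeted gene in every library. Arid3a (ENSMUSG00000019564, mm10 chromosome 10, 79927043 to 79955018, plus strand) was not lower in the libraries labelled siArid3a. It had 375, 370 and 391 reads in control libraries 1, 2 and 3, and 380, 367 and 376 reads in siArid3a libraries 1, 2 and 3. The level scaled to library size was 19.6 ± 2.94 CPM in the controls (SD, n = 3) and 19.3 ± 2.49 CPM in the libraries labelled siArid3a (SD, n = 3). The log2 fold change was −0.03 (SE 0.13, edgeR adjusted p = 0.943), with a 95% interval from −0.31 to 0.26, or 0.80 to 1.20 times the control level. A two-sided exact permutation test gave p = 0.8, where 3 against 3 libraries cannot go below 0.1. The transcript thus goes against the labels, and each direction below is that of the libraries labelled siArid3a, not of measured Arid3a loss.

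The second comparison asked which transcripts differ after transfection with siRNA against Arid3a. No single gene passed the edgeR test, while genes of the interferon response, inflammation and glycolysis were lower as groups in the libraries labelled siArid3a and DNA replication genes were higher. These group calls come from camera at a preset correlation, and none of the 4 lists passed with an estimated correlation (adjusted p = 0.503 for each) or with fry. The genes with the smallest p, none of them past the threshold, included the actin-binding protein gene Avil at 13.7 ± 2.81 CPM in the controls and 27.7 ± 5.52 CPM in the libraries labelled siArid3a, and the carbonic anhydrase gene Car6 at 16.7 ± 1.26 and 34.0 ± 9.77 CPM (SD, n = 3 each). Of 13234 genes tested, edgeR called 0 at an adjusted p under 0.05 and 0 at 2-fold or more. The smallest adjusted p was 0.0747. At an unadjusted p under 0.05 there were 1976 genes, where evenly spread p-values would give 662. That number is no measure of chance for these libraries, since a split that mixed the groups gave 2095 genes. With 1 library left out the count was 1077 to 2397. The groups did not overlap in 2651 genes (20.03%), where the average over all splits of 3 against 3 libraries is 10%. That share was not computed for the splits that mix the groups, so it is no measure of chance either. limma-voom also called 0 genes, and DESeq2 called 223, of which 107 were higher, 116 lower and 12 changed at least 2-fold. Without a filter on low counts edgeR called 439 genes, and with each library's GC and length trend removed, chosen after seeing the data, it called 408.

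Of the 10 genes with the smallest p, 6 had higher values in the libraries labelled siArid3a and 4 lower. Avil (chromosome 10, 127000709 to 127020994) had a log2 fold change of 1.02 (SE 0.16), and Car6 (chromosome 4, 150187015 to 150201332) of 1.03 (SE 0.16), both with an edgeR adjusted p of 0.0747. Of the exonic bases of Avil, 58.8% lie outside other genes. The log2 fold change was 0.86 (SE 0.14) for the membrane protein gene Tmem47, 0.65 (SE 0.12) for Ung, whose product removes uracil from DNA, and 0.81 (SE 0.15) for Map2, a microtubule-associated protein gene. Klf5, a zinc-finger transcription factor gene of proliferating smooth muscle, had 29.1 ± 0.733 CPM in the controls and 42.6 ± 6.28 CPM in the libraries labelled siArid3a (SD, n = 3), a log2 fold change of 0.55 (SE 0.11). Among the genes with lower values, Frmd4b had a log2 fold change of −1.12 (SE 0.22), the chemokine scavenger receptor gene Ackr3 of −0.54 (SE 0.10), Tmem176b of −0.48 (SE 0.09) and the retinal reductase gene Dhrs3 of −0.47 (SE 0.09). DESeq2 called all 10 of these genes, with adjusted p from 3.6e-06 for Avil and Car6 to 0.0047 for Klf5.

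**Figure D1:**
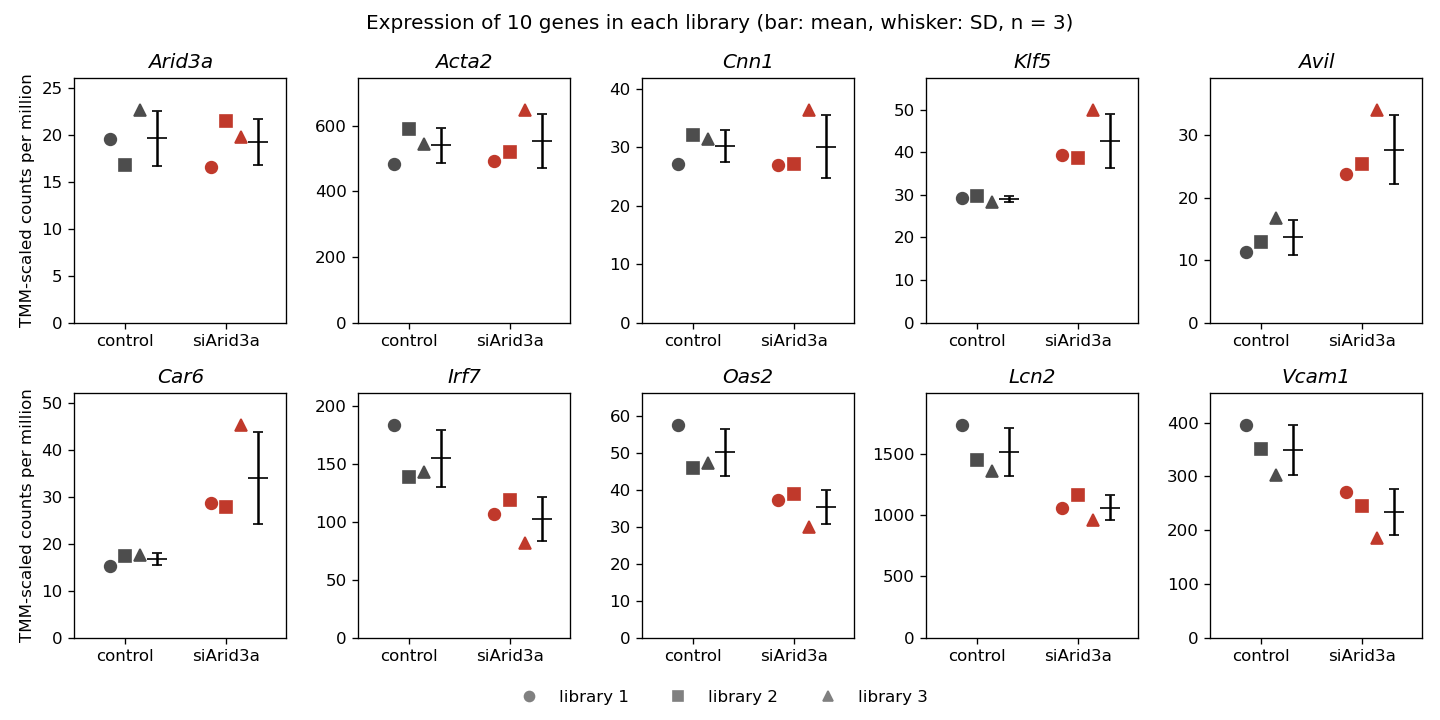
TMM-scaled CPM (vertical axes, from 0) of 10 genes in each control library (grey) and each library labelled siArid3a (red); symbols mark the library number, and bars with whiskers give the mean and SD of 3 libraries. Arid3a lies at 19.6 CPM in the controls and 19.3 CPM in the libraries labelled siArid3a, and Avil, Car6, Klf5, Irf7, Oas2, Lcn2 and Vcam1, picked for small p-values, have groups that do not overlap.

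Interferon-stimulated genes, the antiviral response program, were lower as a group. Of 50 tested, 48 had a log2 fold change below 0, with a median of −0.37, and 32 fell and 0 rose when adjusted over the list alone, against 0 over all genes tested. The abundant members Ifitm3 and Ifit1, inhibitors of viral entry and translation, had log2 fold changes of −0.36 (SE 0.10) and −0.36 (SE 0.13). Among members singled out after their values were seen, Irf7, a transcription factor of the interferon response, went from 154.8 ± 24.7 to 102.5 ± 18.8 CPM and Oas2, a sensor of double-stranded RNA, from 50.1 ± 6.34 to 35.3 ± 4.7 CPM (SD, n = 3). Irf1 had a log2 fold change of −0.41 (SE 0.10), and the immunoproteasome subunit genes Psmb8 and Psmb9 of −0.77 (SE 0.21) and −1.14 (SE 0.26), with 44.5% of the exonic bases of Psmb8 outside other genes. DESeq2 called 11 members, all lower, with Irf7, Oas2, Irf1, Psmb8, Psmb9 and Ifitm3 among them but not Ifit1. The camera test gave an adjusted p of 1.0e-20 at a preset correlation of 0.01, and the list did not pass with an estimated correlation (adjusted p = 0.503). The median deviation from the control mean was −0.30, −0.17 and −0.58 in siArid3a libraries 1, 2 and 3, and 0.17, −0.04 and −0.12 in control libraries 1, 2 and 3.

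Cytokine, chemokine and NF-kB response genes were also lower as a group. Of 45 tested, 33 lay below 0, with a median log2 fold change of −0.31, and 19 fell and 1 rose when adjusted over the list alone, against 0 over all genes. Saa3, an acute-phase protein gene and the most abundant member, had 4176 ± 953 CPM in the controls and 2762 ± 376 CPM in the libraries labelled siArid3a, and Csf1, a macrophage growth factor gene, had 1639 ± 151 and 1909 ± 77.1 CPM (SD, n = 3). DESeq2 called 6 members, all lower. Of these, chosen after their values were seen, the log2 fold change was −0.52 (SE 0.10) for the siderophore-binding protein gene Lcn2, −0.58 (SE 0.12) for the leukocyte adhesion gene Vcam1, −0.53 (SE 0.13) for the complement gene C3 and −0.43 (SE 0.11) for the neutrophil chemokine gene Cxcl1. The camera adjusted p was 5.8e-08, and the list did not pass with an estimated correlation (adjusted p = 0.503). Its median deviation was −0.18, −0.19 and −0.39 in siArid3a libraries 1, 2 and 3, and 0.18, −0.06 and −0.08 in control libraries 1, 2 and 3.

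Glycolysis and hypoxia-response genes followed with 28 of 33 tested members below 0 and a median log2 fold change of −0.21. Adjusted over the list alone, 13 fell and 0 rose, against 0 over all genes. Pkm, the pyruvate kinase gene, had 2396 ± 13.2 CPM in the controls and 1966 ± 131 CPM in the libraries labelled siArid3a, and Gapdh had 4415 ± 236 and 3877 ± 332 CPM (SD, n = 3). Of the 5 members called by DESeq2, all lower, Pdk1, Pfkl and Tpi1 were picked after their values were seen and had log2 fold changes of −0.43 (SE 0.10), −0.42 (SE 0.10) and −0.28 (SE 0.08). The camera adjusted p was 1.6e-07 (adjusted p = 0.503 with an estimated correlation). The median deviation was −0.16, −0.14 and −0.26 in siArid3a libraries 1, 2 and 3, against 0.02, −0.05 and 0.01 in control libraries 1, 2 and 3.

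Matrix proteases and their inhibitors had a median log2 fold change of −0.17 over 34 genes, 26 of them below 0. None passed over the list alone (0 of 34) or over all genes, with Ctsb at −0.20 (SE 0.08) and Timp2 at −0.14 (SE 0.09), and the camera adjusted p was 0.0047 (adjusted p = 0.503 with an estimated correlation). The median deviation of the protease list was −0.04, −0.11 and −0.29 in siArid3a libraries 1, 2 and 3 and 0.01, −0.06 and 0.03 in control libraries 1, 2 and 3, so siArid3a library 1 lay within the control range. Collagen, elastic fibre and other matrix genes had a median of −0.07 over 40 genes, of which 5 fell when adjusted over the list alone. The most abundant matrix genes did not pass: Fn1 had 4917 ± 793 and 5394 ± 586 CPM, and Fbln2 had 2084 ± 278 and 1992 ± 279 CPM (SD, n = 3). The lysyl oxidase family gene Loxl3, chosen after its value was seen, had a log2 fold change of −0.46 (SE 0.09). The deviation of the matrix list was −0.04, 0.04 and −0.20 in siArid3a libraries 1, 2 and 3 and 0.05, −0.13 and 0.09 in the controls, so only siArid3a library 3 lay outside the control range. The matrix list had a camera adjusted p of 0.0287 (adjusted p = 0.779 with an estimated correlation). It did not pass without control library 1 (adjusted p = 0.188), control library 3 (adjusted p = 0.223) or siArid3a library 3 (adjusted p = 0.456), where the median was −0.04, −0.02 and −0.02. Nor did it pass with the depth block (median −0.01, adjusted p = 0.444) or the GC and length trend removed (median −0.02, adjusted p = 0.272), both chosen after seeing the data.

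E2F targets and DNA replication genes were higher as a group. Of 46 tested, 35 lay above 0, with a median log2 fold change of 0.12, and 3 rose and 0 fell when adjusted over the list alone, against 0 over all genes. Pcna, the replication clamp gene, had 455.0 ± 38.2 CPM in the controls and 520.9 ± 34.7 CPM in the libraries labelled siArid3a (SD, n = 3), and the helicase gene Mcm2 a log2 fold change of 0.12 (SE 0.09). The cyclin gene Ccne2, chosen after its value was seen, had a log2 fold change of 0.54 (SE 0.15), and 37.1% of its exonic bases lie outside other genes. The camera adjusted p was 3.1e-04 (adjusted p = 0.503 with an estimated correlation), and the median deviation was 0.04, 0.10 and 0.15 in siArid3a libraries 1, 2 and 3 and −0.03, 0.00 and 0.00 in the controls. G2 and mitotic genes did not pass, with a median of −0.04 over 49 genes (camera adjusted p = 0.244), Top2a at −0.05 (SE 0.08) and Anln at −0.04 (SE 0.08). Replication histone genes had a median of −0.13 over 31 genes (camera adjusted p = 0.324), with H1f2 at −0.21 (SE 0.09) and H2bc4 at −0.31 (SE 0.12). Whether polyA capture holds the histone transcripts in full was not tested, so these values are no measure of histone expression or of replication. The p53 targets and cyclin-dependent kinase inhibitors had a median of −0.01 over 37 genes (camera adjusted p = 0.513), with Ccnd2 at −0.01 (SE 0.08) and Plk2 at 0.03 (SE 0.08), while Gadd45a, chosen after its value was seen and with 51.3% of its exonic bases outside other genes, had 0.41 (SE 0.09). In the p53 list 1 gene rose when adjusted over the list alone.

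Unfolded protein and ATF4 response genes had a median log2 fold change of 0.08 over 35 genes, 27 of them above 0, and 1 rose when adjusted over the list alone. The endoplasmic reticulum chaperone gene Hspa5 had 1193 ± 26.5 and 1366 ± 131 CPM, and Phgdh, an enzyme gene of serine synthesis, 946.7 ± 72.0 and 1031 ± 55.1 CPM (SD, n = 3). Ppp1r15a, whose product directs dephosphorylation of eIF2 alpha, was singled out after its value was seen and had a log2 fold change of 0.45 (SE 0.10). The camera adjusted p was 0.0039 (adjusted p = 0.503 with an estimated correlation). The median deviation was 0.0283, 0.063 and 0.153 in siArid3a libraries 1, 2 and 3 and −0.0319, 0.0014 and 0.0286 in the controls, so siArid3a library 1 lay within the control range. Genes of the mitochondrial genome had a median of 0.15 over 22 genes, 0 of them past the threshold over the list alone, with COX1 at 0.05 (SE 0.10) and CYTB at 0.13 (SE 0.11). Their camera adjusted p was 0.0017 (adjusted p = 0.581 with an estimated correlation), and it was 0.623 without control library 3, 0.155 with the depth block and 0.377 with the GC and length trend removed. The median of voom log2 fold changes, 0.20 over all 6 libraries, was then 0.02, 0.06 and 0.01. The median deviation of this list was 0.25, 0.06 and 0.29 in siArid3a libraries 1, 2 and 3, within the control values of −0.01, 0.38 and −0.33. The mitochondrial share of all counts was 2.78%, 3.23% and 2.37% in control libraries 1, 2 and 3 and 3.04%, 2.81% and 3.06% in siArid3a libraries 1, 2 and 3.

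**Figure D2:**
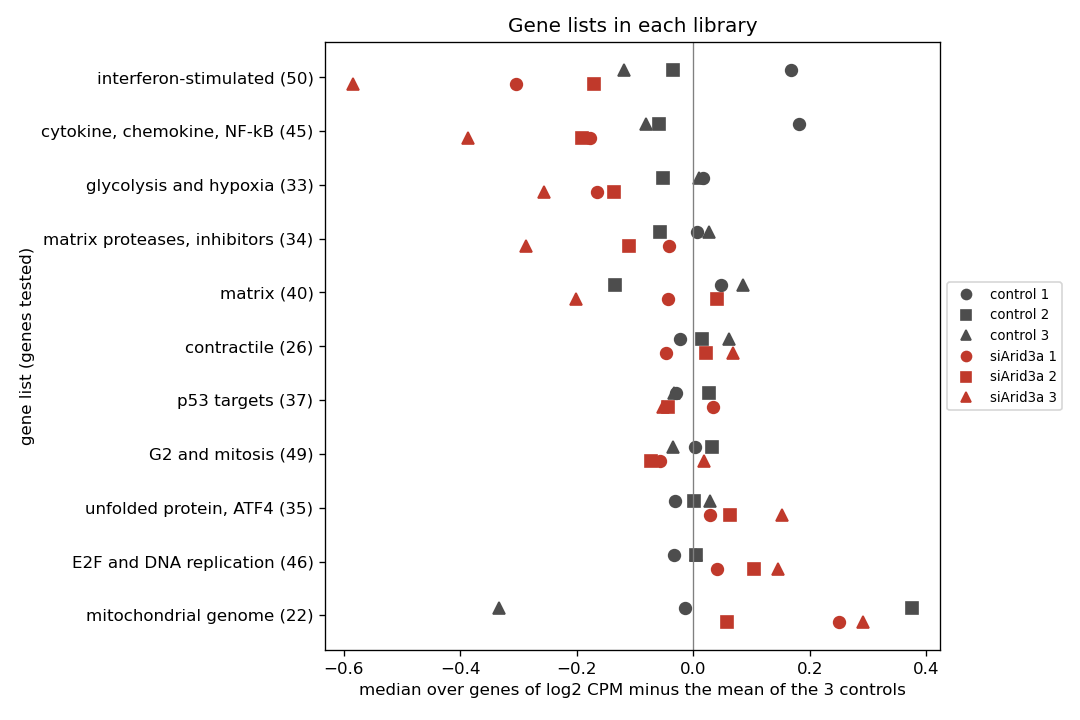
Median over the genes of 11 lists of log2 CPM minus the mean of the 3 controls (horizontal axis, log2 units) in each library, with control libraries in grey and libraries labelled siArid3a in red; the number of genes tested stands beside each list name. For interferon-stimulated genes the libraries labelled siArid3a lie at −0.30, −0.17 and −0.58, below the 3 control libraries, and siArid3a library 3 lies farthest out.

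Smooth muscle contractile genes did not pass as a group, with 13 of 26 above 0 and 13 below, a median log2 fold change of −0.00 and a camera adjusted p of 0.575. Acta2, smooth muscle actin, had 540.6 ± 53.7 CPM in the controls and 553.9 ± 82.7 CPM in the libraries labelled siArid3a, and Cnn1, calponin, had 30.2 ± 2.72 and 30.1 ± 5.38 CPM (SD, n = 3). Flna and Cald1, the most abundant members, had log2 fold changes of −0.01 (SE 0.09) and 0.14 (SE 0.09). Tagln had 1.46 ± 0.306 and 1.22 ± 0.402 CPM, and 32.1% of its exonic bases lie outside other genes. Myh11, smooth muscle myosin heavy chain, was too low to be tested, with 30 reads over the 6 libraries. The sign of Acta2 turned with the depth block, that of Cnn1 with the GC and length trend removed and that of Flna with both.

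None of the other lists of smooth muscle biology and general cell state passed the camera test. Growth factor and immediate early genes had a median log2 fold change of −0.05 over 50 genes (camera adjusted p = 0.720), with Igfbp7 at −0.28 (SE 0.09) and Igfbp3 at −0.17 (SE 0.09). Of this list 2 genes rose and 2 fell when adjusted over the list alone, and Fos and Fosb, chosen after their values were seen, had −0.53 (SE 0.13) and −0.61 (SE 0.14). TGF-beta genes had a median of 0.04 over 33 genes (camera adjusted p = 0.932), with Ltbp2 at −0.09 (SE 0.13). YAP and TAZ targets had a median of 0.04 over 24 genes (camera adjusted p = 0.118), with Axl at −0.00 (SE 0.09) and Ankrd1 at 0.15 (SE 0.09). Osteogenic and chondrogenic genes had a median of 0.04 over 14 genes (camera adjusted p = 0.932), with Spp1 at −0.05 (SE 0.09) and Bmp4 at −0.25 (SE 0.10). Angiotensin receptor, enzyme and signalling genes had a median of 0.07 over 12 genes (camera adjusted p = 0.193), with Ece1 at 0.05 (SE 0.08) and Atp6ap2 at 0.10 (SE 0.07). In that list 1 gene rose when adjusted over the list alone, and it was Agt, angiotensinogen, chosen after its value was seen, at 2.84 ± 1.55 and 5.73 ± 0.491 CPM (SD, n = 3).

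Sterol genes had a median log2 fold change of −0.08 over 29 genes (camera adjusted p = 0.0788), with Fasn at 0.08 (SE 0.10) and Scd2 at −0.38 (SE 0.10), and 1 gene fell when adjusted over the list alone. Apoptosis regulators had a median of −0.06 over 28 genes (camera adjusted p = 0.193), with Cycs at 0.21 (SE 0.11) and Mcl1 at 0.03 (SE 0.07), and 1 gene rose and 2 fell when adjusted over the list alone. Antioxidant and iron genes had a median of −0.01 over 33 genes (camera adjusted p = 0.796), with the ferritin genes Fth1 at −0.14 (SE 0.09) and Ftl1 at −0.01 (SE 0.08). Genes of RNA interference and double-stranded RNA sensing had a median of −0.02 over 20 genes (camera adjusted p = 0.932), with Xpo5 at 0.09 (SE 0.08) and Eif2ak2 at 0.00 (SE 0.07). Nuclear respiratory chain genes had a median of −0.03 over 73 genes (camera adjusted p = 0.324), with Atp5b at 0.03 (SE 0.08) and Atp5a1 at −0.14 (SE 0.08). Ribosomal protein genes had a median of −0.01 over 72 genes (camera adjusted p = 0.932), with Rplp0 at 0.03 (SE 0.09) and Rpsa at −0.04 (SE 0.09). The AT-rich interaction domain genes had a median of 0.00 over 12 genes (camera adjusted p = 0.961), with Arid5b at −0.02 (SE 0.08) and Kdm5a at 0.03 (SE 0.07). The sign of the median differed from that of the camera test for the contractile and neural lists, and the sign of the mean differed for the TGF-beta, AT-rich interaction domain and endothelial lists.

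Lists of markers of other cell types that a smooth muscle culture can hold were tested as well. Which cells held these transcripts was not measured, so a lower list does not show fewer cells of that type. Pericyte markers had a median log2 fold change of −0.31 over 7 genes, of which 3 fell when adjusted over the list alone, with Pdgfrb at −0.32 (SE 0.12) and Cspg4 at −0.01 (SE 0.14). The pericyte list had a camera adjusted p of 0.0226 (adjusted p = 0.503 with an estimated correlation), and without siArid3a library 3 it did not pass (adjusted p = 0.155). The median of voom log2 fold changes went from −0.31 over all 6 libraries to −0.05 without siArid3a library 3. Its median deviation was 0.04, −0.14 and −0.53 in siArid3a libraries 1, 2 and 3 and 0.13, −0.12 and −0.05 in the controls. Macrophage and leukocyte markers had a median of −0.43 over 7 genes, of which 1 fell when adjusted over the list alone, with Cd14 at −0.45 (SE 0.11) and Cd53 at −0.06 (SE 0.15). Epithelial and mesothelial markers had a median of −0.29 over 6 genes, of which 1 fell when adjusted over the list alone, with Msln at −0.19 (SE 0.08) and Krt19 at −0.39 (SE 0.10). In siArid3a libraries 1, 2 and 3 the median deviation was −0.25, −0.25 and −0.66 for the macrophage list and −0.23, −0.20 and −0.41 for the epithelial list, against 0.22, 0.09 and −0.13 and −0.10, 0.13 and −0.08 in the controls. Both lists had a camera adjusted p of 0.0434 (adjusted p = 0.503 with an estimated correlation). The macrophage list did not pass without control library 1, control library 2, siArid3a library 2 or siArid3a library 3 (adjusted p = 0.166, 0.113, 0.0565 and 0.13), nor the epithelial list without control library 2 or siArid3a library 2 (adjusted p = 0.278 and 0.115). Scaled by library size alone neither passed (adjusted p = 0.0568 for both), nor did the macrophage list over genes outside other genes (adjusted p = 0.0685) or the epithelial list with the CPM filter or the GC and length trend removed (adjusted p = 0.0698 and 0.101). The median of voom log2 fold changes of the macrophage list, −0.41 over all 6 libraries, was −0.23, −0.24 and −0.24 without control library 1, control library 2 and siArid3a library 3. It was −0.46 without siArid3a library 2, −0.43 with library size alone and −0.37 over genes outside other genes. For the epithelial list, −0.29 over all 6 libraries, it was −0.24 without control library 2, −0.32 without siArid3a library 2, −0.30 with library size alone, −0.18 with the CPM filter and −0.25 with the trend removed.

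The remaining marker lists did not pass. Fibroblast markers had a median log2 fold change of −0.10 over 13 genes (camera adjusted p = 0.142), with Fn1 as above and Dcn, decorin, at 518.8 ± 74.7 and 371.0 ± 55.2 CPM (SD, n = 3), and 2 genes fell when adjusted over the list alone. Endothelial markers had a median of −0.22 over 7 genes (camera adjusted p = 0.459), with Eng at −0.34 (SE 0.13) and Vwf at −0.22 (SE 0.19). Adipocyte markers had a median of 0.19 over 6 genes (camera adjusted p = 0.322), with Lpl at 0.30 (SE 0.11) and Dgat2 at 0.33 (SE 0.12). Neuron and Schwann cell markers had a median of −0.19 over 5 genes (camera adjusted p = 0.324), with Map2 at 0.81 (SE 0.15) and Ncam1 at 0.37 (SE 0.11), and 2 genes rose when adjusted over the list alone. Skeletal and cardiac muscle markers had a median of −0.16 over 4 genes (camera adjusted p = 0.796), with Tnnt2 at 0.17 (SE 0.21) and Tnnt3 at −0.21 (SE 0.54).

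The third comparison set each library labelled siArid3a against the 3 controls, with the spread taken from the controls alone. It called 199 genes in siArid3a library 3, of which 83 were higher and 116 lower, and 0 genes in library 1 and in library 2, where 660 and 472 genes had an unadjusted p under 0.05. Scaled by library size alone, library 3 gave 85 genes. The log2 fold change of Arid3a was −0.24 (SE 0.19), 0.13 (SE 0.19) and 0.01 (SE 0.19) in libraries 1, 2 and 3. On the first principal component, with 34.1% of the variance, siArid3a library 3 lay at 32.2 and the other libraries between −17.4 and 5.85. The edgeR test of 1 library compares that library with the controls, not the conditions, since a lone library is assumed to vary like the controls. The counts of calls in the group comparison were 132, 100 and 44 without control library 2, control library 3 and siArid3a library 2, and 0 without each of the other 3 libraries.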

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

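The depth block, the GC and length correction and the restriction to genes outside other genes were chosen after seeing the data. The count of called genes stayed at 0 with RLE, upper quartile and library-size scaling, limma-voom, the CPM filter, a non-robust fit, the stricter threshold and the restriction. It was 223 with DESeq2, 439 without a filter, 408 with the GC and length trend removed and 105 with the depth block, and 0 to 132 with 1 library left out. The counts changed at least 2-fold were 12, 23, 13 and 5, and 0 to 9. Of the 223 genes called by DESeq2, all 223 had the same sign and an unadjusted p under 0.05 in edgeR, 221 were also called without the filter, 173 with the trend removed and 93 with the depth block. The edgeR fits differed in their median prior degrees of freedom, the weight given to the spread shared between genes. It was 8.02 to 11.1 in the fits with 0 calls and at least 14.1 in the fits with calls. Without the filter it was infinite, so those calls rest on the shared spread. The causes were not tested. The lists past the threshold numbered 11, and 0 with an estimated correlation and 0 with fry, whose test does not compare a list with other genes. They numbered 9 to 14 in the other settings, where the interferon, inflammatory, glycolysis, replication, unfolded protein and protease lists passed in each. Splits that mix the groups gave 1 to 13 lists. Single siArid3a library 3 gave 199 genes, and 85 with library size only.

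Same-numbered libraries did not deviate together (r = 0.03, −0.179 and −0.085), so the numbers were not taken as pairs. With the replicate block edgeR called 0 genes, 0 at 2-fold, and 11 lists passed.

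The log2 fold change of Arid3a was 0.0698 with the depth block, 0.0382 with the GC and length trend removed, and −0.1281 to 0.0836 with 1 library left out, without passing in any setting. Of 1797 values of 101 other genes, named or analysed beside them, under the alternatives, 1509 kept their sign and their side of the threshold, 218 gained a call with their sign and 70 reversed, the cause of which was not tested. With DESeq2 and with RLE, Flna was 0.0003 and Axl 0.0013. Eif2ak2 was −0.0133 with library size, −0.0117 with upper quartile and −0.0009 without a filter. With limma-voom Cspg4 was 0.0036 and Tnnt3 0.0564. With the trend removed Cnn1 was 0.0303, Flna 0.0508, Fbln2 0.0116, Axl 0.0598, Ftl1 0.0404, Kdm5a −0.0384, Eif2ak2 −0.0435, Cspg4 0.0623 and COX1 −0.0507. With the depth block Acta2 was −0.0184, Flna 0.0333, Fbln2 0.0256, Ltbp2 0.049, Axl 0.0355, Ftl1 0.012, Arid5b 0.0226, Eif2ak2 −0.0152 and Cspg4 0.1309. With 1 library left out the ranges were −0.0911 to 0.1132 for Acta2, −0.1596 to 0.0708 for Cnn1, −0.0429 to 0.0595 for Flna, −0.1728 to 0.0445 for Fbln2, −0.033 to 0.015 for Ccnd2, −0.0195 to 0.0753 for Plk2, −0.2186 to 0.0219 for Ltbp2, −0.0454 to 0.0489 for Axl, −0.0131 to 0.1829 for Fasn, −0.0458 to 0.0104 for Ftl1, −0.0244 to 0.1337 for Ece1, −0.0728 to 0.0387 for Arid5b, −0.0108 to 0.0669 for Kdm5a, −0.0086 to 0.0602 for Mcl1, −0.0203 to 0.0397 for Eif2ak2, −0.1879 to 0.0653 for Cd53, −0.1645 to 0.1106 for Cspg4, −0.0174 to 0.4135 for Tnnt2, −0.6102 to 0.3099 for Tnnt3, −0.0109 to 0.0878 for Rplp0, −0.0815 to 0.0241 for Rpsa, −0.0343 to 0.1376 for COX1 and −0.008 to 0.0521 for Atp5b.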

Other observations

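The tests of leukocytes, of exchanged labels, of overlapping reads, of depth, of depth as a block and of the splits for called genes and for 2-fold calls were chosen after the results were seen. Several genes outside the lists, chosen after their values were seen, were called by DESeq2 and not by edgeR. Lower in the libraries labelled siArid3a were Apol8, an apolipoprotein L gene, at 4.01 ± 0.353 and 1.78 ± 0.234 CPM, Trim14, whose product takes part in antiviral signalling, at 2.82 ± 0.44 and 1.28 ± 0.37 CPM, and the complement protease gene C1s1 at 54.4 ± 7.52 and 35.2 ± 6.46 CPM (SD, n = 3 each, controls first). The exonic bases outside other genes were 48.6% for Trim14 and 19.7% for C1s1. Higher were Tdg, a DNA glycosylase gene of active demethylation, at 24.4 ± 3.54 and 36.0 ± 2.3 CPM, and Neto2 at 10.8 ± 1.09 and 17.7 ± 3.21 CPM. The pericyte marker Steap4 had a log2 fold change of −0.49 (SE 0.12).

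The angiotensin receptor gene Agtr1a had 2 reads over the 6 libraries together, which hold 17029735 to 22799935 counts each. Arid3b, the relative of Arid3a, had 5 reads, but only 3.99% of its exonic bases lie outside other genes, so its level is not known from these counts. Across genes the log2 fold change and GC content had a Spearman correlation of −0.27; genes are not independent replicates.

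Arid3a was not lower in the libraries labelled siArid3a. If transfection lowered Arid3a, an exchange of labels between the groups needs libraries with low Arid3a among the controls. The lowest of the 6 libraries had 0.732 of the highest. If transfection did not lower it, exchanged labels would leave Arid3a level too, so this test cannot decide that case and an exchange stays open there. Reads of another gene are argued against by the annotation, where 100% of the exonic bases of Arid3a lie outside other genes, and low depth by the lower bound of the 95% interval, −0.315 on the log2 scale, far above the −1 of a fall to 0.5 of the control level. The plain reading, that the transfection did not lower the transcript, stays open. So do intronic reads within the counted span, a difference in protein alone and a recovery of the transcript by the time of harvest. Libraries labelled wrongly against samples outside the series stay open too, and these tables test none of these.

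Interferon-stimulated and inflammatory genes were lower in all 3 libraries labelled siArid3a, with a median log2 fold change of −0.341 over the 95 members tested. A trend with GC content or transcript length is argued against by the median after its removal, −0.333, and −0.413 to −0.229 with 1 library left out. An effect of siArid3a library 3 alone is argued against, by a narrow margin, by the other 2 libraries labelled siArid3a. Of these the higher median against the 3 controls was −0.177, below the range of −0.152 to 0.252 of each control against the other controls. The references of the 2 sides thus differ, and control library 1, at 0.252, raises that of the siArid3a libraries. With 1 library left out the median before removal of the trend was −0.410 to −0.229. The macrophage, pericyte and epithelial marker lists moved the same way (medians −0.43, −0.31 and −0.29). All 7 tested macrophage and leukocyte markers lay below 0, with Cd14 at 54.5 and 39.8 CPM and Cd53 at 13.2 and 12.6 CPM (controls first). Leukocytes as carriers of the lost RNA are thus argued against by level only, not by direction. In the controls 9 leukocyte genes, Ptprc and Tyrobp among them, had at most 0.596 CPM, and Lyz2 had 5.17 CPM. The interferon and inflammatory lists together lost 4052 CPM, or 2637 CPM without Saa3, whose groups overlap. For those 9 genes the share of exonic bases outside other genes is not given, so reads lost in shared spans could lower their counts. For Cd53 that share is 100%. The siRNA treatment, indirect effects of other cells and differences in culture between the groups stay open and were not tested, and with Arid3a not lower the data do not link the pattern to Arid3a.

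The smooth muscle genes Myh11, Mylk and Des were near the detection limit, with 30, 64 and 81 reads over the 6 libraries, while Acta2 had 64322. Loss of reads to overlapping genes is argued against for Myh11, where 100% of the exonic bases lie outside other genes. It stays open in part for Mylk and Des, where 75.3% and 90.2% do. A dedifferentiated culture or another mesenchymal cell type is open, and no biological explanation was tested.

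The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 called genes and the highest other 2, and for 2-fold calls both were 0. With a real value of 0 all 10 of the 10 splits must give as many, so these counts say nothing about chance. At an unadjusted p under 0.05 the real split gave 1976 genes and the highest other 2095, with 2 of 10 splits as high. That split, also the one with 2 called genes, put together control libraries 1 and 3 and siArid3a library 2, which have both the 3 lowest totals and the 3 lowest mitochondrial shares. Depth and mitochondrial share cannot be separated here, and control library 1 and siArid3a library 3 are close in depth, at 19079970 and 19585920 counts. With this split as a block the comparison of the groups gave 105 genes. For lists past the threshold the real split gave 11 and the highest other 13, with 2 of 10 splits as high. The other splits gave 9, 10, 8, 13, 9, 1, 6, 3 and 4 lists, so camera also called many lists in splits that mix the groups.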
